A study of Mus musculus with 6 samples.

How the data were processed

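RNA was measured in heart ventricles of mice at postnatal day 14, in 3 control and 3 Cend1-KO libraries. Groups and replicate numbers (1, 3 and 4 in each group) were taken from the sample titles. The names of the deposited columns carry other numbers: the Cend1-KO column numbered 3 holds replicate 4, not replicate 3. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit, which is not stated to mark strand. The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries, which may be partly technical.

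Per the submitters' processing notes, CASAVA, fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used with the mm10 mouse genome build. How expression values were computed from the read counts, and which gene annotation was used, are not given in the sources used here. The deposited table holds TPM values (transcript abundances scaled by length and library) made by the authors, although its name speaks of counts: the values are not whole and each library sums to 1000000. Columns were matched to libraries through the sample descriptions, since for most libraries the number in the column name differs from that in the title. TPM keeps no sequencing depth, so the depth per library is unknown and no counting interval or detection floor is given. TPM values are relative within a library: a library in which a few transcripts take more of the total has lower values for all other genes.

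The table lists 57010 gene identifiers. Symbols, coordinates and exonic lengths came from GENCODE M21, on the same genome build, and 52029 identifiers matched. Of 5966 genes with a mean of at least 10 TPM, 6 were listed at exactly 0 in at least 1 library. One of them was Nnt, for which the table has 2 overlapping identifiers, so a value of 0 is described here as listed at 0. Reads of near-identical copies, such as the hemoglobin, H2-Q and interferon-inducible GTPase genes and the 7 nuclear copies of mitochondrial genes on chromosome 1, may have been split between copies by the authors' counting, and values of such single genes are uncertain.

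The design fixed before the data were examined assumed read counts and named limma on log2(value + 1) for a table without counts, which was used. Genes with at least 1 TPM in at least 3 libraries were tested, which left 13542 genes, 200 of them without a symbol. The values were used as deposited with a pseudocount of 1 TPM, and limma 3.58.1 in R 4.3.3 was fitted with a mean-variance trend and a robust prior. Differences are Cend1-KO minus control on the log2(TPM + 1) scale, which understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. On simulated data with 13519 genes tested, this fit recovered 24% of genes changed by 1 on the log2 scale and 83% of genes changed by 2, with 2 false calls. The simulation gave each gene independent noise without shifts of whole libraries, and changed only genes with a mean log2(TPM + 1) above 2. The real libraries did shift, with median-of-ratios factors from 0.714 to 1.24, so these rates may not hold for the calls below.

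A total of 44 gene lists was fixed before the data were examined, and the 41 lists with at least 5 tested members were compared with all other tested genes by camera with a preset correlation of 0.01. Lists are described with their members where camera called the list and at least 1 member was called, and the others are given by their median and p. Genes are named by a rule fixed at the same time: Cend1 and Kdm1a; the 12 highest and 12 lowest differences among called genes with a gene symbol that is not a model name, at least 1 TPM in a group and groups that do not overlap; up to 4 members of each described list with the smallest p; Myh6, Myh7, Nppa, Nppb, Tnni1, Tnni3, Ccnd1, Ccnd2, Cdkn1a and Mki67; and the 3 most abundant called genes in each direction. Genes outside the rule are named as such. Some genes that the rule takes are not reported here. Calls within 5 Mb of Cend1 were compared with calls elsewhere by a two-sided Fisher's exact test.

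Each result was recomputed after median-of-ratios and upper-quartile scaling, without the filter, without the robust prior, with the replicate number as a block, with a loess correction for gene length (span 0.3), with mitochondrial and hemoglobin genes removed, without each library in turn, and with camera's estimated correlation and fry. Pseudocounts of 0.1 and 0.5 TPM, filters at 0.1 and 5 TPM, a fit without the trend, removal of the nuclear mitochondrial copies, Xist as a covariate and median-of-ratios scaling without Cend1-KO replicate 3 were added after the data were seen. Alternatives that need counts (count models, their normalization factors and filters, and voom) were not run.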

Results

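Transcripts of heart ventricles were measured by RNA sequencing in 3 control and 3 Cend1-KO mouse libraries taken at postnatal day 14. Cend1 is a gene named for cell cycle exit and neuronal differentiation, and the series title places it downstream of the histone demethylase LSD1, the product of Kdm1a, in heart regeneration. The comparison asks which transcripts differ in the ventricle when Cend1 is deleted. Values are the authors' TPM, which keep no sequencing depth, so the depth of each library is unknown. Between 12494 and 13925 genes reached 1 TPM in a library. Libraries of one group correlated across genes with Pearson coefficients between 0.971 and 0.988, and libraries of different groups between 0.955 and 0.978, so the ranges overlapped. Of the pairs of one group, only Cend1-KO replicates 1 and 3 (0.971) lay within the range of different groups.

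The libraries differed in a few abundant transcripts. Mitochondrial-genome genes took 19.2% ± 0.81 of TPM in controls (SD, n = 3), and 17.9%, 34.9% and 22.9% in Cend1-KO replicates 1, 3 and 4. Nuclear copies of mitochondrial genes on chromosome 1 took another 8.94% ± 0.51 in controls and 17.3% in Cend1-KO replicate 3, so that both together made 52.1% of that library. Hemoglobin genes took 0.247% ± 0.172 in controls and 1.56% ± 0.77 in Cend1-KO (SD, n = 3 each). Xist, an X-inactivation transcript named after its values were seen, was at 16.4 TPM in control replicate 4 and 7.37 in Cend1-KO replicate 1, and under 0.06 in the other libraries. The Y-linked Ddx3y and Eif2s3y, also named afterwards, were at most 0.0302 TPM in those libraries. In the others they were at 23.1 to 25.6 and 42.6 to 55.6 TPM. By these transcripts both groups held female and male libraries, while the labels give no sex. As deposited, the median difference over all genes was -0.11 on the log2 scale, and 0.0020 after median-of-ratios scaling. List medians below are given relative to the median of all genes.

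**Figure D1:**
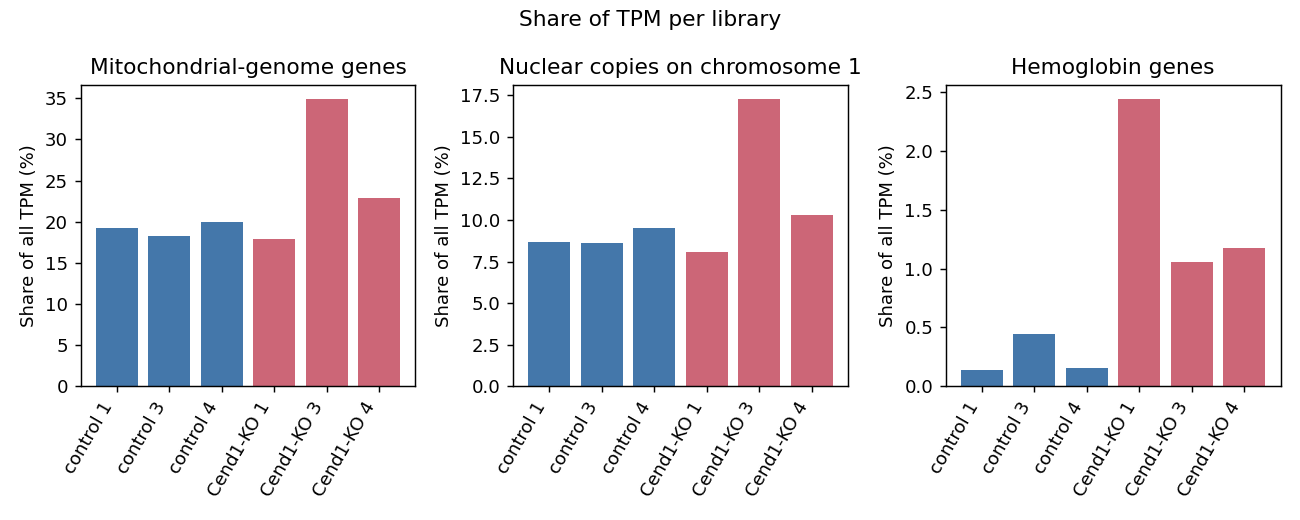
Share of all TPM (y axis, percent) taken by mitochondrial-genome genes, by their nuclear copies on chromosome 1 and by hemoglobin genes, with 1 bar per library (control blue, Cend1-KO red, number: replicate). Cend1-KO replicate 3 had the highest mitochondrial share, 34.9%, and the hemoglobin share was higher in the 3 Cend1-KO libraries, at 1.06% to 2.44%, than in the controls, at 0.138% to 0.445%.

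Cend1 (ENSMUSG00000060240; mm10 chromosome 7, 141426446 to 141429491, minus strand, 1775 bp of exons) was measured at 1.44, 1.99 and 1.54 TPM in control replicates 1, 3 and 4 and was listed at 0 in all 3 Cend1-KO libraries. The difference was -1.40 (SE 0.17) on the log2(TPM + 1) scale, with adjusted p = 0.00111 (limma). No annotated gene overlaps it. With no filter on low genes its adjusted p was 0.0742. Kdm1a was at 16.7 ± 1.19 TPM in controls and 12.9 ± 3.33 in Cend1-KO (SD, n = 3 each; adjusted p = 0.503), a difference that did not pass the test.

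Of 13542 genes tested, 230 differed between Cend1-KO and control, 107 higher (46.5%) and 123 lower, and 206 of them by at least 2-fold. Cell-cycle genes and Tnni1, the slow skeletal troponin I of the immature heart, were among the lowest, and interferon-induced, hemoglobin and adipocyte genes among the highest. All 230 called genes had groups that did not overlap, as had 24.3% of all tested genes, where chance gives 10%. After median-of-ratios scaling 1396 genes were called, 836 higher (59.9%) and 560 lower, and 227 of the 230 were among them. Leaving out Cend1-KO replicate 3 gave 825 calls, 219 of them shared. With no filter 30114 genes were tested and limma called 0, with 2894 at an unadjusted p under 0.05. Of the named genes, 23 that were not called as deposited were called after median-of-ratios scaling, and Gapdh and Myl1 lost their call. Of the 48 called genes that the naming rule takes besides Cend1, 23 stayed called whichever library was left out, namely Cfd, Mt2, Ifit3, Hp, Ifit1, Fmo2, Gsta3, Adipoq, Retn, Ifi44, Lyve1, Nmrk2, Rrm2, Tnni1, H2-Q6, H2-Q7, Ube2c, Rrad, Ccnb1, Cdca8, Ckap2l, Cks2 and Plk1. The other 25 lost their call without at least 1 library. Without control replicate 1, control replicate 3 or Cend1-KO replicate 4 the calls fell to 113, 76 and 110, and without Cend1-KO replicate 1 they rose to 669.

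**Figure D2:**
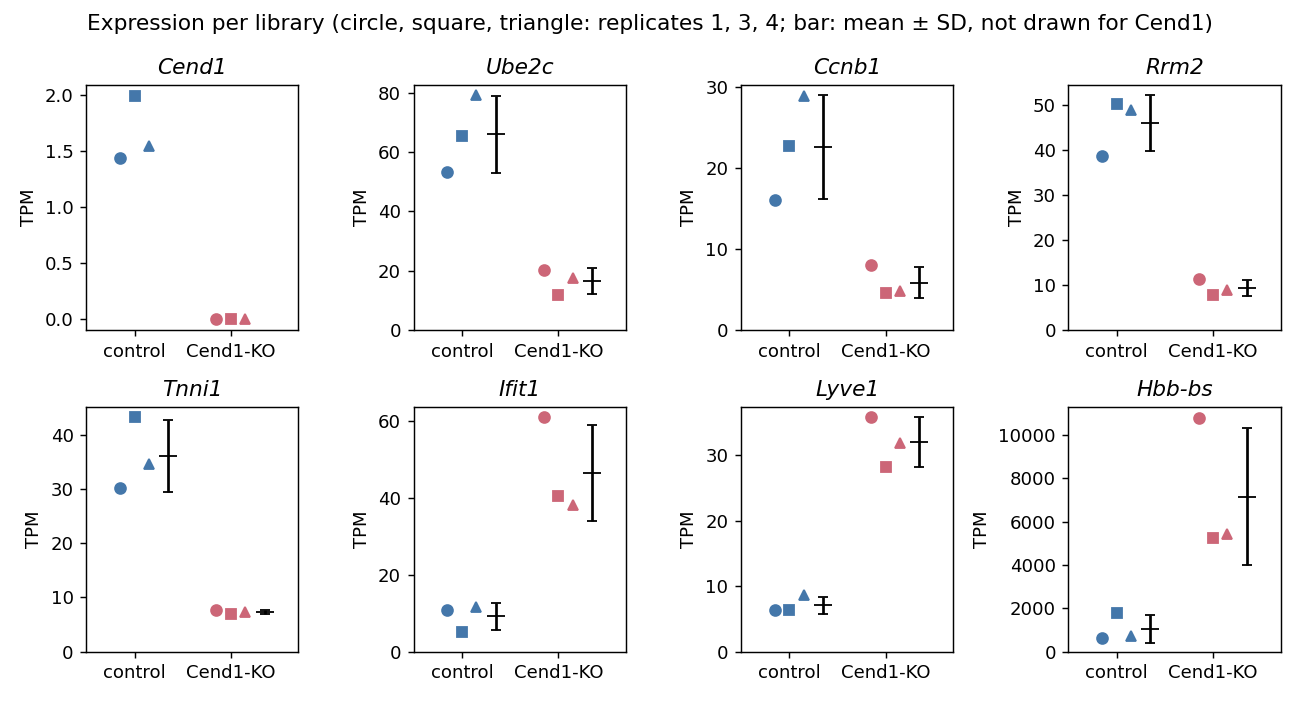
TPM (y axis) of 8 genes in each control (blue) and Cend1-KO (red) library, with symbols for replicates 1, 3 and 4 and bars for the mean ± SD of 3 libraries (not drawn for Cend1). Cend1 is at 0 in the 3 Cend1-KO libraries, Ube2c, Ccnb1, Rrm2 and Tnni1 are lower in each Cend1-KO library than in any control, and Ifit1, Lyve1 and Hbb-bs are higher.

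Of 36 genes of the G2 phase and mitosis, 20 fell in Cend1-KO ventricles and 0 rose, all 36 fell when adjusted over the list alone, and 33 fell after median-of-ratios scaling. The 20 became 9 without control replicate 3, 12 without Cend1-KO replicate 4 and 33 without Cend1-KO replicate 1. The list median was -1.09 (camera adjusted p = 4.56e-30; adjusted p = 0.479 with an estimated correlation). After median-of-ratios scaling the median difference from the control mean was -0.93, -1.09 and -1.19 in Cend1-KO replicates 1, 3 and 4, where the erythroid, fibroblast and endothelial medians were above every control. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, went from 66.1 ± 13.1 to 16.5 ± 4.24 TPM (SD, n = 3 each; adjusted p = 0.00255). Cyclin B1 (Ccnb1) went from 22.6 ± 6.41 to 5.83 ± 1.92 TPM (adjusted p = 0.00762). The kinase Plk1 went from 7.49 ± 1.68 to 1.71 ± 0.733 TPM (adjusted p = 0.00736). Ckap2l, Cdca8, Cdc20 and Cks2 fell as well, with log2 differences of -1.72, -1.77, -1.71 and -1.68. Mki67, a marker of cycling cells, was at 5.43 ± 1.53 and 2.50 ± 0.662 TPM (adjusted p = 0.114, and 0.0207 after median-of-ratios scaling).

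Of 32 tested S-phase and replication genes, 2 fell as deposited, 23 when adjusted over the list alone and 19 after median-of-ratios scaling. Without Cend1-KO replicates 1, 3 and 4 the 2 became 21, 6 and 1, and without any one control 1. Their list median was -0.57 (camera adjusted p = 9.32e-13; adjusted p = 0.542 with an estimated correlation). After median-of-ratios scaling it was -0.52, -0.66 and -0.64 from the control mean in Cend1-KO replicates 1, 3 and 4. The erythroid, fibroblast and endothelial medians were above every control there, and the adult sarcomere median of replicate 1 was lower still, at -0.79. The genes that fell were Rrm2, a subunit of ribonucleotide reductase, from 46.0 ± 6.29 to 9.38 ± 1.81 TPM (SD, n = 3 each; adjusted p = 7.09e-04), and cyclin E1 (Ccne1), from 3.09 ± 0.282 to 1.11 ± 0.347 TPM (adjusted p = 0.0340). Cdt1 and E2f1 had adjusted p = 0.0518 and 0.0582, and 0.00468 and 0.00332 after median-of-ratios scaling. Of 11 G1 drivers, 1 fell, again Ccne1, both over all genes and adjusted over the list alone, and 3 fell after median-of-ratios scaling or without Cend1-KO replicate 1, and 0 without any one control or Cend1-KO replicate 4. The list median was -0.34 (camera adjusted p = 0.0279; adjusted p = 0.738 with an estimated correlation). Ccnd1 was at 29.8 ± 10.8 and 24.8 ± 14.6 TPM (adjusted p = 0.683), and Ccnd2 at 31.2 ± 4.87 and 19.9 ± 4.41 (adjusted p = 0.253, and 0.0477 after median-of-ratios scaling). Cdk2 and Cdk4 had adjusted p = 0.281 and 0.377, and 0.0340 and 0.115 after median-of-ratios scaling. Of 21 cell-cycle inhibitors and exit genes 0 were called as deposited, with a list median of 0.030 (camera adjusted p = 0.960). After median-of-ratios scaling 2 rose, Cdkn1c and Ccng2, and 1 fell, Cdkn2d (adjusted p = 0.0143, 0.0101 and 0.00468, named after their values were seen), and as deposited without Cend1-KO replicate 3 the counts were also 2 and 1, and without Cend1-KO replicate 1 they were 0 and 2. Cdkn1a was at 43.9 ± 3.99 and 41.9 ± 7.45 TPM (adjusted p = 0.911).

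Medians of several lists of cardiac muscle genes were lower. After median-of-ratios scaling the erythroid, fibroblast and endothelial medians were above every control in all 3 Cend1-KO libraries, and replicate 1 had the lowest adult sarcomere median, -0.79, and the highest endothelial median, 1.18. Sftpc, a lung transcript, was at 437.5, 0.107 and 702.9 TPM in Cend1-KO replicates 1, 3 and 4. Of 16 fetal-type cardiac genes 3 fell, 8 fell and 1 rose when adjusted over the list alone. Without Cend1-KO replicate 3 there were 5 that fell, and without control replicate 1 or 3 there was 1. The fetal-type list median was -0.44 (camera adjusted p = 0.00126; adjusted p = 0.479 with an estimated correlation). Tnni1 went from 36.1 ± 6.68 to 7.33 ± 0.333 TPM (SD, n = 3 each; adjusted p = 7.09e-04), the atrial natriuretic peptide gene Nppa from 430.4 ± 103.5 to 172.4 ± 26.7 (adjusted p = 0.0150), and Tnnt1 from 72.1 ± 13.6 to 28.4 ± 11.4 (adjusted p = 0.0387). Myl7 was at 3.10 ± 0.655 and 8.78 ± 4.15 TPM (adjusted p = 0.102). Myh6 and Myh7, the cardiac myosin heavy chains, had log2 differences of -0.75 and -0.73 (adjusted p = 0.182 and 0.243), Nppb -0.46 (adjusted p = 0.611) and Tnni3 -0.49 (adjusted p = 0.285). Of 20 adult sarcomere genes limma called 0 over all genes, 8 fell when adjusted over the list alone, 1 after median-of-ratios scaling and 6 without Cend1-KO replicate 3. The sarcomere list median was -0.44 (camera adjusted p = 3.74e-07; adjusted p = 0.542 with an estimated correlation). Of 20 cardiac transcription factors 1 fell, Ppargc1a, a coactivator of mitochondrial genes (adjusted p = 0.0219), 2 adjusted over the list alone and 3 after median-of-ratios scaling, and 3 and 2 fell without Cend1-KO replicates 1 and 3. The factor list median was -0.32 (camera adjusted p = 0.00127; adjusted p = 0.729 with an estimated correlation). Ppara, Gata4 and Tbx20 had adjusted p = 0.117, 0.165 and 0.179, of which Gata4 and Tbx20 reached 0.0160 and 0.0322 after that scaling. Of 22 calcium and ion channel genes 1 fell, the calcium channel subunit Cacnb2 (adjusted p = 0.0383), also adjusted over the list alone, and 3 fell and 1 rose after median-of-ratios scaling. Without Cend1-KO replicate 1, 3 fell, and without Cend1-KO replicate 3, 1 fell and 1 rose. The calcium list median was -0.27 (camera adjusted p = 0.00662; adjusted p = 0.650 with an estimated correlation). Kcne1, Kcnh2 and Kcnj2 had adjusted p = 0.164, 0.189 and 0.192, of which Kcne1 and Kcnh2 reached 0.0369 and 0.0295 after scaling. Of 9 skeletal-muscle markers 1 fell, Myl1, from 119.6 ± 17.1 to 54.8 ± 10.9 TPM (adjusted p = 0.0292), and 2 adjusted over the list alone, with a list median of -0.40 (camera adjusted p = 0.0166; adjusted p = 0.650 with an estimated correlation). After median-of-ratios scaling the median was -0.38 (adjusted p = 0.0908) and the log2 difference of Myl1 -0.98 (adjusted p = 0.0600; -1.12 as deposited), and without control replicate 4 the median was 0.014. Casq1, Mybpc2 and Tnni2 had adjusted p = 0.0759, 0.438 and 0.559.

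Of 22 glycolysis genes 1 fell, 14 when adjusted over the list alone and 4 after median-of-ratios scaling, 5 and 6 without Cend1-KO replicates 1 and 3, and 0 without control replicate 1, control replicate 3 or Cend1-KO replicate 4. The glycolysis list median was -0.49 (camera adjusted p = 5.51e-08; adjusted p = 0.542 with an estimated correlation). Gapdh went from 244.5 ± 18.1 to 111.1 ± 42.7 TPM (SD, n = 3 each; adjusted p = 0.0359), a log2 difference of -1.19, and of -1.05 after median-of-ratios scaling (adjusted p = 0.113). Pgam2, Pfkp and Pfkm had adjusted p = 0.0980, 0.136 and 0.145, of which Pfkp reached 0.0182 after scaling. The glycolysis and fatty acid oxidation medians were lowest in Cend1-KO replicate 1, at -0.68 and -0.60 after scaling, where the endothelial median was highest. Of 30 fatty acid oxidation genes 1 fell, 6 when adjusted over the list alone, 3 and 8 without Cend1-KO replicates 1 and 3, and 0 without control replicate 1 or 3. The oxidation list median was -0.36 (camera adjusted p = 2.33e-06; adjusted p = 0.542 with an estimated correlation). Acot2, a mitochondrial thioesterase, went from 74.5 ± 5.02 to 30.8 ± 2.35 TPM (adjusted p = 0.0117), and Cpt1b, Acsl1 and Hadha had adjusted p = 0.0521, 0.0918 and 0.10. Nmrk2, a nicotinamide riboside kinase of muscle, had the lowest log2 difference of the named genes, -2.46 (20.5 ± 2.99 and 2.90 ± 0.284 TPM, adjusted p = 2.77e-04). Rrad, a GTPase of striated muscle, went from 143.1 ± 17.1 to 40.8 ± 15.4 TPM (adjusted p = 0.00663). The 3 most abundant genes that fell were Hopx (633.1 and 290.6 TPM, adjusted p = 0.0477), Tuba1b (476.9 and 212.0, adjusted p = 0.0203) and Nppa. H2-Q6 and H2-Q7, class I histocompatibility genes with near-identical copies, went from 5.53 ± 0.611 to 0.582 ± 0.339 and from 5.42 ± 0.686 to 0.578 ± 0.377 TPM (adjusted p = 7.02e-04 and 7.65e-04).

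Of 25 interferon-stimulated genes 8 rose, 17 did not pass the test and 0 fell, 21 rose when adjusted over the list alone and 21 after median-of-ratios scaling, and 24 rose without Cend1-KO replicate 3, 3 without control replicate 1 or 3 and 4 without Cend1-KO replicate 4. Without Cend1-KO replicate 1, 8 rose and 1 fell. The list median was 1.04 (camera adjusted p = 1.16e-22; adjusted p = 0.479 with an estimated correlation). Ifit1 went from 9.25 ± 3.54 to 46.6 ± 12.6 TPM (SD, n = 3 each; adjusted p = 0.00270), Ifit3 from 20.1 ± 9.42 to 102.3 ± 39.2 (adjusted p = 0.00663), Ifi44 from 3.51 ± 0.342 to 14.4 ± 5.71 (adjusted p = 0.00948) and Gbp3 from 18 ± 2.8 to 58.0 ± 26.8 (adjusted p = 0.0208). The surfactant transcript Sftpc, a lung marker of a list fixed beforehand, was at 437.5 TPM in Cend1-KO replicate 1, 702.9 in replicate 4, 0.107 in replicate 3 and listed at 0 in the controls.

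Of 32 fibroblast and matrix genes 2 rose, 9 when adjusted over the list alone and 16 after median-of-ratios scaling, 4 and 10 without control replicate 4 and Cend1-KO replicate 3, 1 without Cend1-KO replicate 1, and 0 without control replicate 1 or 3. The 2 genes called as deposited, Mfap5 and Lum, were not among the 10 called without Cend1-KO replicate 3. The fibroblast list median was 0.67 (camera adjusted p = 2.22e-13; adjusted p = 0.542 with an estimated correlation). Mfap5 went from 120.3 ± 42.5 to 308.8 ± 116.9 TPM and Lum from 200.8 ± 87.7 to 490.4 ± 97.9 (SD, n = 3 each; adjusted p = 0.0364 and 0.0372), and Dcn and Postn had adjusted p = 0.0591 and 0.104, and 0.0164 and 0.0298 after scaling. Of 22 macrophage and myeloid markers 1 rose, 4 when adjusted over the list alone, 7 after median-of-ratios scaling, 10 without Cend1-KO replicate 3 and 2 without control replicate 4. The myeloid list median was 0.39 (camera adjusted p = 5.19e-06; adjusted p = 0.650 with an estimated correlation). Lyve1, a hyaluronan receptor also found on lymphatic endothelium, went from 7.08 ± 1.30 to 32.1 ± 3.84 TPM (adjusted p = 0.00108), and Cd163, F13a1 and Lyz2 had adjusted p = 0.0703, 0.0795 and 0.126, and 0.00473, 0.00336 and 0.0207 after scaling. Of 21 endothelial markers 0 were called over all genes or adjusted over the list alone and 8 rose after median-of-ratios scaling, with a list median of 0.66 (camera adjusted p = 1.24e-07; adjusted p = 0.650 with an estimated correlation). Of 19 Hippo-YAP targets 1 rose and 1 fell, also adjusted over the list alone, and 3 rose and 1 fell after median-of-ratios scaling. The Hippo-YAP list median was 0.47 (camera adjusted p = 0.00427; adjusted p = 0.738 with an estimated correlation). Ccn2, a matrix-associated growth factor, rose (adjusted p = 0.0196), Birc5, which is also a mitotic gene, fell (adjusted p = 0.0140), and Axl and Fstl1 had adjusted p = 0.182 and 0.198, and 0.00954 and 0.0186 after scaling. Of 5 Schwann cell markers 1 rose, Cdh19 (adjusted p = 0.0124), also adjusted over the list alone, and 2 after median-of-ratios scaling, with a list median of 0.48 (camera adjusted p = 0.00275; adjusted p = 0.479 with an estimated correlation), and Cnp and Pmp22 had adjusted p = 0.421 and 0.519, of which Cnp reached 0.0328 after scaling. Of 6 valve and cartilage-like markers 1 rose, Cytl1 (adjusted p = 0.0255), and 2 adjusted over the list alone or after median-of-ratios scaling, with a list median of 0.25 (camera adjusted p = 0.0171; adjusted p = 0.542 with an estimated correlation, and 0.0750 after median-of-ratios scaling, where the median was also 0.25). Cilp, Fmod and Comp had adjusted p = 0.147, 0.865 and 0.866, of which Cilp reached 0.0197 after scaling. Of 21 immediate early genes 1 fell, Nr4a3 (adjusted p = 0.0429), also adjusted over the list alone, while the list median was 0.43 (camera adjusted p = 8.12e-04; adjusted p = 0.729 with an estimated correlation), and Klf6, Klf2 and Klf4 had adjusted p = 0.148, 0.182 and 0.185. After median-of-ratios scaling 5 rose and 1 fell, with adjusted p = 0.00427, 0.0146 and 0.0184 for Klf6, Klf2 and Klf4, and without Cend1-KO replicate 3 as deposited 4 rose and 1 fell, and 7 rose and 1 fell with both. Sftpc was high in Cend1-KO replicates 1 and 4, at 437.5 and 702.9 TPM.

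Some blood and fat transcripts were higher in Cend1-KO. Of 11 erythroid genes 4 rose, 7 rose and 1 fell when adjusted over the list alone, and 7 rose and 0 fell after median-of-ratios scaling. The erythroid list median was 1.99 (camera adjusted p = 2.14e-09; adjusted p = 0.479 with an estimated correlation). Without Cend1-KO replicate 3, limma called 0 of the 11 as deposited and 3 after scaling, and the log2 differences of Hbb-bs, Hbb-bt and Alas2 were 3.03, 2.98 and 2.48 as deposited, against 2.85, 2.78 and 2.26 with all libraries. Without control replicate 1 or 3 alone, 2 and 6 rose. The beta-globins Hbb-bs and Hbb-bt, near-identical copies, went from 1051.2 ± 653.8 to 7138.6 ± 3156.8 and from 488.6 ± 328.0 to 3138.4 ± 1456.3 TPM (SD, n = 3 each; adjusted p = 0.00575 and 0.0125), and Alas2 had adjusted p = 0.0486. Of 9 adipocyte markers 3 rose, Cfd, Adipoq and Retn, and 4 rose and 1 fell when adjusted over the list alone, with a list median of 0.75 (camera adjusted p = 3.45e-05; adjusted p = 0.479 with an estimated correlation). Cfd was at 0.0352 ± 0.0609 and 9.22 ± 3.86 TPM, and Adipoq at 0.449 ± 0.716 and 4.92 ± 0.485 (adjusted p = 1.31e-04 and 0.00226). Retn had adjusted p = 0.00398, and Fabp4, which endothelium also expresses, 0.0776 (0.00955 after scaling). Other genes among the highest were Spp1, Mt2, Hp, Fmo2 and Gsta3, with log2 differences of 2.81, 2.72, 2.26, 2.17 and 2.16. Spp1 lost its call without Cend1-KO replicate 1 or 3 (difference 2.91 and 3.16, adjusted p = 0.118 and 0.0672). In addition, Ly6c1 was among the most abundant, at 187.8 and 573.9 TPM (adjusted p = 0.0290).

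**Figure D3:**
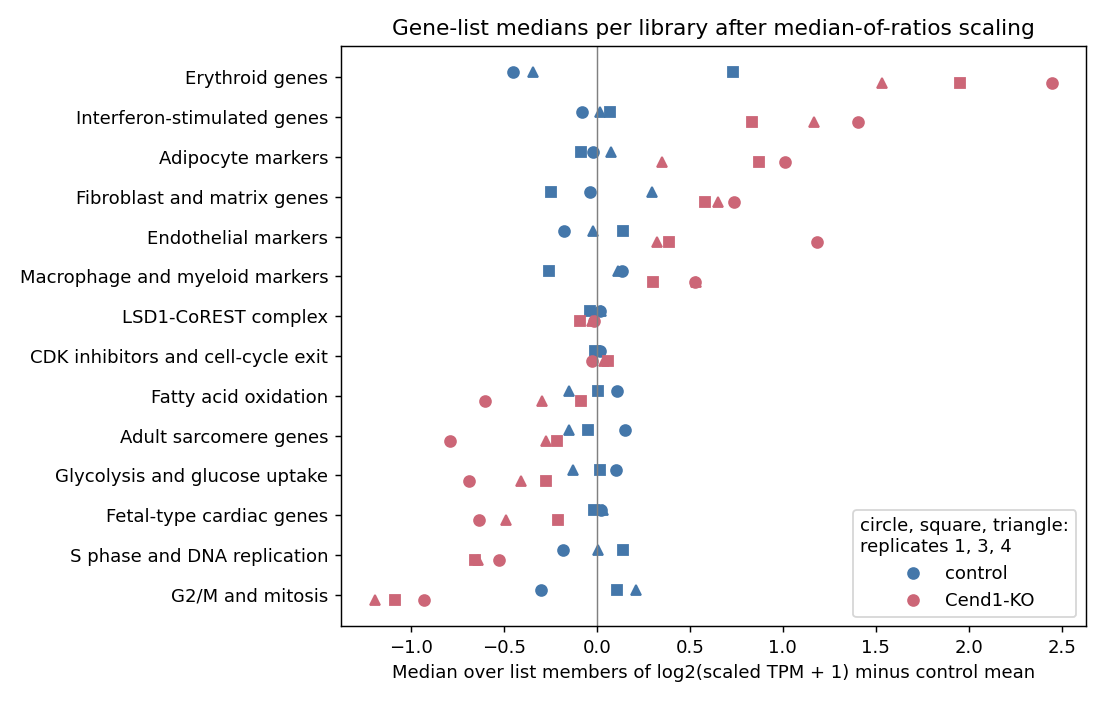
Median over the members of each gene list (rows) of log2(scaled TPM + 1) minus the control mean (x axis) in each library after median-of-ratios scaling, control blue and Cend1-KO red, with symbols for replicates 1, 3 and 4. The G2/M median is -0.93 to -1.19 in the Cend1-KO libraries and -0.30 to 0.21 in controls, and the interferon-stimulated median is 0.83 to 1.41 against -0.079 to 0.074.

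The calls in the calcium, transcription factor, skeletal-muscle, Schwann, valve and immediate early lists were lost without control replicate 1 or 3, as was the rise in the Hippo-YAP list, whose fall was lost without control replicate 3. Without Cend1-KO replicate 4 the calcium, transcription factor, skeletal-muscle and immediate early lists held 0 calls by limma, and without control replicate 4 the calcium and skeletal-muscle lists. Without Cend1-KO replicate 3 there were 2 that fell in the skeletal-muscle list, 2 that rose in the Schwann and Hippo-YAP lists and 1 in the endothelial list. In the adipocyte list 1 member fell without Cend1-KO replicate 1 or 3, and in the fetal-type list 1 rose without Cend1-KO replicate 1. In all, camera called 28 of 41 lists, 13 up and 15 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.479. Further lists called without a described member were nuclear-encoded oxidative phosphorylation (median -0.26, adjusted p = 1.01e-05), the TCA cycle (-0.32, adjusted p = 5.16e-04), heat shock proteins (-0.26, adjusted p = 0.00662), cytosolic ribosomal proteins (-0.21, adjusted p = 0.0171), sterol synthesis (-0.28, adjusted p = 0.0498), the unfolded protein response (0.35, adjusted p = 0.0112), epicardial markers (0.62, adjusted p = 0.0419) and mitochondrial-genome genes (0.44, adjusted p = 9.44e-05). Without Cend1-KO replicate 3, 4 heat shock genes and 1 gene of the TCA cycle fell and 1 of the unfolded protein response rose, and without Cend1-KO replicate 1, 1 sterol gene fell. With an estimated correlation the adjusted p of these lists were 0.729, 0.542, 0.650, 0.911, 0.796, 0.743, 0.779 and 0.650. After median-of-ratios scaling the ribosomal, epicardial and mitochondrial-genome lists were not called (adjusted p = 0.0750, 0.275 and 0.0750), with medians of -0.19, 0.62 and 0.47. The epicardial median was 1.31 in control replicate 4, above each Cend1-KO library (0.41 to 0.82), and 7 of 11 members rose without that control, and the mitochondrial-genome median was -0.39, 1.54 and 0.39 in Cend1-KO replicates 1, 3 and 4. Not called were lists for the LSD1-CoREST complex (adjusted p = 0.802), p53 targets (0.363), the ATF4 response (0.444), hypoxia (0.783), circadian genes (0.304), pericytes (0.551), neutrophils (0.540), lymphocytes (0.960), neurons (0.850), atrial markers (0.977) and conduction markers (0.453). Too few members were tested for camera in the lung, liver and sex-linked lists, at 2, 4 and 4, with medians of -0.18, 1.20 and 0.17. The lung median covers only Hopx, which is abundant in these ventricles, and Napsa. The filter took out lung markers that were high in Cend1-KO replicates 1 and 4 only, such as Sftpc (437.5 and 702.9 TPM). The median therefore does not show that lung transcripts were unchanged.

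Genes around Cend1 were examined for linked differences. Within 5 Mb, 0 of 85 tested genes were called by limma, against 227 of 13256 elsewhere (two-sided Fisher's exact test, p = 0.408). After median-of-ratios scaling 5 of the 85 were called, against 1366 of 13256 (two-sided Fisher's exact test, p = 0.212). Cdkn1c, named above among the cell-cycle inhibitors, was 1 of these 5. Within 20 Mb, 2 of 227 tested genes were called as deposited, 1 of them Plk1, against 225 of 13114 elsewhere. The list of genes next to Cend1 had a median of 0.038 (camera adjusted p = 0.783).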

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

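Pseudocounts of 0.1 and 0.5, filters at 0.1 and 5 TPM, the fit without a trend, removal of nuclear mitochondrial copies, Xist as a covariate, and median-of-ratios scaling without Cend1-KO replicate 3 or with an estimated correlation were chosen after seeing the data. Alternatives that need counts were not run, namely count models with their factors and filters, and voom. Scaling to library size alone is the deposited TPM, and the planned filter at 1 CPM has its counterpart in the filter used. The number of called genes, 230, depended on the scaling, the filter and the libraries. It was 1396 (836 higher, 560 lower, 353 at least 2-fold, 5 near Cend1) after median-of-ratios scaling, 1405 (823 higher, 582 lower, 349 at least 2-fold, 5 near Cend1) after upper-quartile scaling, 485 (285 higher, 200 lower, 316 at least 2-fold, 1 near Cend1) with mitochondrial and hemoglobin genes removed, 1032 (755 higher, 277 lower, 471 at least 2-fold, 4 near Cend1) with their nuclear copies removed too, 538 (297 higher, 241 lower, 340 at least 2-fold, 1 near Cend1) with the Xist covariate and 1368 (801 higher, 567 lower, 363 at least 2-fold, 9 near Cend1) after median-of-ratios scaling without Cend1-KO replicate 3. These settings kept 227, 227, 226, 225, 229 and 225 of the 230 calls in the same direction, of which 228 were tested where mitochondrial and hemoglobin genes were removed. A filter at 5 TPM gave 116 calls (55 higher, 61 lower, 114 at least 2-fold), and a filter at 0.1 TPM 81 lower. With no filter limma called 0 genes in any of these classes and the targeted gene Cend1 lost its call (difference -1.40, adjusted p = 0.0742, and 5.59e-05 to 0.00997 in the other settings but the replicate blocks): the genes tested rose from 13542 to 30114 and the highest prior degrees of freedom fell from 9.64 to 3.19. Adjusted p under 0.01 and under 0.1 gave 58 and 425 genes, and within 20 Mb of Cend1 there were 2 calls.

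Without 1 library at a time the calls ranged from 76 (control replicate 3) to 825 (Cend1-KO replicate 3), with 39 to 511 higher, 37 to 524 lower, 76 to 366 at least 2-fold and 0 to 5 near Cend1. They were 113, 76 and 248 without control replicates 1, 3 and 4 and 669, 825 and 110 without Cend1-KO replicates 1, 3 and 4. Of the 230 calls, between 71 and 225 stayed called in the same direction. The cause of these shifts was not tested. Of 41 lists, camera called 28 as deposited and 23 after median-of-ratios scaling, and 0 and 0 with an estimated correlation. As deposited fry called 0 by direction and 20 in either direction, and after median-of-ratios scaling 9 and 31.

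Replicate numbers are shared by the groups in the titles but not in the column names. Same-numbered libraries did not deviate together (correlations of -0.17, 0.044 and -0.12 for numbers 1, 3 and 4). Control replicate 4 correlated best with Cend1-KO replicate 1, at 0.20. These were the libraries with Xist at 16.4 and 7.37 TPM, and whether sex accounts for the correlation was not tested. With the title number as a replicate block the calls were 738 (366 higher, 372 lower, 355 at least 2-fold, 4 near Cend1), and with gene-length correction as well 669 (340 higher, 329 lower, 359 at least 2-fold, 5 near Cend1), each with all 230 calls kept. The block leaves fewer degrees of freedom for the spread, yet the adjusted p of Cend1 was 1.31e-09 with it and 0.00111 without (limma). Such small p-values are not credible for 6 libraries, so the block counts are no support for the calls.

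Log2 differences of 4 named genes and medians of 11 lists changed sign, and 1 of these, the skeletal-muscle list, had been called. Ccnd1 (-0.37) had 0.0074 with median-of-ratios scaling without Cend1-KO replicate 3, -0.80 to 0.075 without 1 library. Cdkn1a (-0.076) had 0.061 with median-of-ratios scaling, 0.055 with upper-quartile scaling, 0.064 with mitochondrial and hemoglobin genes removed, 0.17 with nuclear copies removed, 0.0091 with median-of-ratios scaling without Cend1-KO replicate 3, -0.16 to 0.076 without 1 library. Fmod (0.27) had -0.23 to 0.99 without 1 library. Comp (-0.12) had 0.028 with nuclear copies removed, 0.039 with median-of-ratios scaling without Cend1-KO replicate 3, -0.34 to 0.094 without 1 library. CDK inhibitors and cell-cycle exit (0.030) had -0.069 with no filter, -0.017 with filter at TPM 0.1, -0.030 with median-of-ratios scaling without Cend1-KO replicate 3, -0.043 to 0.090 without 1 library. ATF4 and integrated stress response (-0.0055) had 0.0042 with block and length correction, 0.0042 with gene-length correction, 0.0042 with filter at TPM 5, 0.0051 with median-of-ratios scaling without Cend1-KO replicate 3, -0.038 to 0.034 without 1 library. p53 targets (0.015) had -0.11 with no filter, -0.0038 with nuclear copies removed, -0.059 with filter at TPM 0.1, -0.0075 to 0.079 without 1 library. Circadian clock genes (0.032) had -0.054 with no filter, -0.00069 with filter at TPM 0.1. Pericyte and smooth-muscle markers (0.096) had -0.037 with no filter. Neutrophil markers (-0.19) had 0.064 with no filter, 0.053 with mitochondrial and hemoglobin genes removed, 0.024 with nuclear copies removed, 0.078 with filter at TPM 0.1, 0.15 with median-of-ratios scaling without Cend1-KO replicate 3, -0.31 to 0.16 without 1 library. Lymphocyte markers (0.026) had -0.0063 with median-of-ratios scaling, -0.0062 with upper-quartile scaling, -0.040 with no filter, -0.047 with mitochondrial and hemoglobin genes removed, -0.039 with nuclear copies removed, -0.0015 with pseudocount 0.1, -0.035 to 0.23 without 1 library. Neuronal genes (-0.28) had 0.0086 with no filter, 0.12 with filter at TPM 0.1. Skeletal-muscle markers (-0.40) had -0.76 to 0.014 without 1 library. Atrial markers (0.016) had -0.077 with filter at TPM 0.1, -0.22 with median-of-ratios scaling without Cend1-KO replicate 3, -0.26 to 0.23 without 1 library. Genes next to Cend1 (0.038) had -0.00053 with median-of-ratios scaling, -0.034 with no filter, -0.022 with nuclear copies removed, -0.0058 with pseudocount 0.1, -0.0051 with filter at TPM 0.1, -0.029 with filter at TPM 5, -0.044 to 0.062 without 1 library. The cause was not tested. TPM keeps no depth, so which low genes are limited by read number is unknown.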

Other observations

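Tests of explanations below, the marker counts and the family sums were chosen after the results were seen. The gene lists were fixed before the data were examined.

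Single-library values of transcripts of other tissues differed between the Cend1-KO libraries. Of 11 lung markers other than Sftpc and Hopx, 8 were above the highest control in Cend1-KO replicate 1, 3 in replicate 3 and 8 in replicate 4, all in TPM after median-of-ratios scaling. As deposited, the alveolar transcript Ager was at 9.69, 0.110 and 34.6 TPM in these libraries, and at 0.121 to 0.140 in controls. Retn and Cfd, adipocyte transcripts, were at 1.55, 2.16 and 2.69 and at 5.10, 12.7 and 9.83 TPM in Cend1-KO replicates 1, 3 and 4. The values of Nnt, a mitochondrial transhydrogenase listed under 2 identifiers, also differed within controls: the identifier ENSMUSG00000116207 was at 121.0 and 126.7 TPM in control replicates 1 and 4, listed at 0 in control replicate 3, and at 22.8, 30.2 and 26.4 in Cend1-KO replicates 1, 3 and 4. The identifier ENSMUSG00000025453 was at 15.9, 138.0 and 5.45 TPM in control replicates 1, 3 and 4, and at 48.8, 39.7 and 41.7 in the Cend1-KO replicates.

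As deposited, 20 of 36 G2/M genes were called lower in the Cend1-KO libraries. Fewer members of the other cell-cycle lists were: 2 of 32 S-phase genes, 1 of 11 G1 drivers and 0 of 21 inhibitor and exit genes. The mitochondrial share of Cend1-KO replicate 3 does not account for the lower G2/M genes as the whole cause, since 32 of 36 were called lower after median-of-ratios scaling without that library. Dilution of heart muscle RNA by other tissue stays open: the gap between the G2/M and adult sarcomere medians lay below the lowest control, -0.45, in 2 of 3 Cend1-KO libraries (-0.87 and -0.92 in replicates 3 and 4, -0.14 in replicate 1). The gap assumes that the G2/M transcripts came from muscle cells, which was not tested. A more advanced stage of development predicts lower G2/M and fetal-type medians, seen in 3 of 3 Cend1-KO libraries, and higher fatty acid oxidation and adult sarcomere medians, seen in 0 of 3; since dilution would lower the latter and litters are not labelled, stage and genotype cannot be told apart. An effect of the deletion itself is a further open explanation.

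Some variable gene families were lower in the Cend1-KO libraries, a pattern noticed in genes outside the naming rule. Summed scaled TPM was 488.0 ± 14 and 258.2 ± 71.6 for 9 H2-K, H2-D and H2-Q genes, 122.3 ± 54.1 and 49.0 ± 7.51 for 5 genes of an interferon-inducible GTPase cluster on chromosome 18, and 129.4 ± 11.4 and 75 ± 20.7 for both Nnt identifiers (control and Cend1-KO, SD, n = 3 each). Reads moved between the summed copies would leave these sums alike only if copies have like lengths and no reads drop out of counting, which was not checked. The sums of 3 of 3 families were lower in each Cend1-KO library than in any control. As the families were chosen after their values were seen, these sums do not decide the question. Gm4951, a member of the GTPase cluster, was higher (4.93, 2.75 and 4.46 TPM in Cend1-KO, 1.82 to 2.01 in controls). Other members overlapped between the groups as deposited, among them H2-D1 (73.7 to 219.5 TPM in Cend1-KO, 175.5 to 216.3 in controls) and Iigp1 (33.6 to 52.9 and 45.0 to 102.2). Lower interferon signalling is argued against by the interferon-stimulated list, whose lowest Cend1-KO library median was 0.83. A different strain background of the groups is a candidate explanation that cannot be told apart from the genotype, since the Nnt ratio of 0.580 raised the idea and all Cend1-KO libraries share the genotype. The Nnt sums also hide a difference within controls: ENSMUSG00000116207 was at 121.0 and 126.7 TPM in control replicates 1 and 4 and listed at 0 in control replicate 3. Whether the controls share 1 background was not tested.

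Interferon-stimulated, fibroblast and endothelial medians were higher than in any control in Cend1-KO replicate 3, at 0.83, 0.58 and 0.39. Lung tissue could bring such transcripts, but 3 of 11 lung markers were above the highest control in that library, which is exactly the highest number counted as arguing against lung, a bound set after the marker levels had been seen, and Sftpc was at 0.107 TPM there. These 3 markers, Ager, Sftpa1 and Sftpb, were at only 0.110, 0.0868 and 0.0131 TPM there as deposited. In Cend1-KO replicates 1 and 4 they were at 9.69, 23.8 and 4.97 TPM or more. For Cend1-KO replicates 1 and 4, where Sftpc was at 437.5 and 702.9 TPM, a contribution of lung RNA to these lists stays open, and the endothelial median of 1.18 in replicate 1 was above those of replicates 3 and 4.

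The 6 libraries can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave the highest count in each case (1 of 10): 230 genes as deposited against at most 27 in another split, 1396 against 4 after median-of-ratios scaling, 206 against 27 for genes changed at least 2-fold, and 28 against 21 for gene lists. The other splits mix the groups, so a group difference adds to their spread and lowers their gene counts. With its preset correlation camera called up to 21 of 41 lists in a mixed split, so its small p-values overstate the evidence for single lists.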
